A study of Mus musculus with 13 samples.

How the data were processed

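Total RNA from the livers of female C57BL6 mice, 12 weeks old, was hybridized to 13 Agilent 4x44K mouse arrays on 5 slides, with a single cyanine dye (Cy3) and 0.1 ug of RNA per labelling. The labels name 3 groups. In 5 samples the mice received the diet labelled HFHS, called the high-fat diet here though the label does not give its composition, with vehicle. In 3 samples they received the standard diet, labelled ST, with vehicle, and in 5 samples the standard diet with a mixture of 4 pollutants, which are not named in the sources used here. The series text can be read as if the mixture had been given in the high-fat diet, while every pollutant sample is labelled with the standard diet. The sample labels were followed.

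Per the file headers, the deposited scanner files hold the intensity of each spot on the linear scale, as extracted by the authors with Agilent Feature Extraction 11.5.1.1. The column used is the processed signal of that program. The authors also deposited a table of normalized values on a log2 scale for 26082 probes, made with limma per the submitters' processing notes. Its scale was taken from the values, and each column of the table matched the scanner file of its own array best (13 of 13). That table was used only as an alternative. Every per-sample column was matched to a sample.

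The processed signal of 39429 probes, with control spots left out and spots that the program marked as outliers set to missing (128 values among the genes tested), was log2-transformed, averaged over the spots of a probe, and each array's 75th percentile was subtracted. A probe was kept if it was well above background on every array of at least 1 group, which left 25029 probes. For each gene the probe with the highest mean over the 13 arrays was used, which gave 19518 genes or unnamed transcripts, 15709 of them with a symbol in the gene table. Symbols came from the accessions in the files, or, where none matched the gene table, from the current or older symbols in them. Probe positions are those of the files, on mouse build mm9. A gene value therefore stands for a single probe, and the values of other probes are given for some of the genes.

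limma 3.58.1 in R 4.3.3 fitted a single model with the 3 groups to all 13 arrays, with moderated variances shared by the groups. Each of the 3 comparisons was a contrast of that model, tested two-sided, with Benjamini-Hochberg adjustment over all 19518 genes, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this limma model unless another test is named. Errors of log2 fold changes are standard errors of the model. The number of arrays, above all the 3 arrays of the ST vehicle group, limits the precision. The 75th percentile of the signal lay between 782 and 1354 intensity units per array, and between 62.8% and 69.5% of the probes were well above background. At most 1 probe per array was saturated.

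Before the data were examined, 19 pathway lists and 13 lists of cell type markers were fixed, along with the groups, the tests, the alternatives and the rule for named genes. The lists were AhR targets, CAR and PXR targets, PPARalpha targets and fatty acid oxidation, lipogenesis, cholesterol synthesis and SREBP2 targets, bile acid synthesis and transport, lipid droplet and PPARgamma targets, glucose metabolism and insulin response, ER stress and amino acid response, NRF2 and antioxidant genes, acute phase and inflammation, interferon response, circadian clock, female-biased and male-biased liver genes, estrogen and steroid hormone handling, oxidative phosphorylation, fibrosis and extracellular matrix, and cell cycle. The markers were those of hepatocytes, the pericentral and the periportal zone, Kupffer cells and macrophages, T cells, B and plasma cells, neutrophils, endothelial cells, cholangiocytes, adipocytes, pancreatic acinar cells, erythroid cells and skeletal muscle. Each of the 32 lists was compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone. An exact permutation test of each list's mean per array was added after the data were seen.

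The named genes of a comparison were the 10 called genes with the largest fold change in each direction that have a symbol other than a clone name and the same sign in every array of the changed group, up to 4 called members of smallest p from each list, and 19 genes of xenobiotic, lipid and hormone metabolism fixed in advance. Not every named gene is given in the text. Of the fixed genes, Cyp1a1 was well above background on 4 arrays and was not tested.

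The pipeline was tested on simulated data, drawn from normal distributions with each gene's mean and moderated spread, with 200 genes changed per comparison. At 1.5-fold, 43.3%, 40.3% and 53.7% of the changed genes were recovered for HFHS against ST vehicle, pollutants against ST vehicle and HFHS against pollutants. At 2-fold these shares were 70.1%, 79.1% and 74.6%, and at 3-fold 87.9%, 84.8% and 86.4%. All recovered genes had the right direction, and between 4.2% and 5.9% of the calls were false. Every value was drawn independently, without a slide effect or correlation between genes. These shares are therefore not the false-call rate of the real arrays.

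The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the authors' table, no filter on dim probes, a filter on all 13 arrays, every probe tested, slide as a fixed or a random block, a replicate block, fits of only the 2 groups compared, a variance trend with robust moderation, array weights, other thresholds, and leaving out each array in turn. Fits without the 3 arrays of slide 1 and without 3 HFHS arrays that carried pancreatic transcripts were added after the data were seen. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on at most 1 array each, in a series labelled female throughout.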

Results

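Liver expression profiles were measured on 13 one-colour arrays from female mice, 5 on the high-fat diet with vehicle (HFHS), 3 on the standard diet with vehicle (ST vehicle) and 5 on the standard diet with a low-dose mixture of 4 pollutants (pollutants). The series title gives the purpose, which was to set the mixture beside a high-fat challenge and look for common and specific features. Arrays of the same group correlated at 0.977 to 0.992 across genes, and arrays of different groups at 0.973 to 0.992. The 5 slides each held HFHS and pollutant arrays, and slides 1, 2 and 5 also held an ST vehicle array. The first principal component (22.8% of the variance) set the 3 arrays of slide 1 (-41.81 to -35.41) apart from the other arrays (-2.27 to 36.71).

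The first comparison asked what the high-fat diet changed, HFHS against ST vehicle (n = 5 and 3). Genes of cholesterol synthesis fell together on the high-fat diet. Of the 24 genes of cholesterol synthesis and SREBP2 targets, 13 fell and 0 rose, and 22 fell adjusted over the list alone. Hmgcs1, the HMG-CoA synthase of the pathway, fell by 1.99 ± 0.27 on the log2 scale (3.96-fold, adjusted p = 0.0115). Idi1 and Nsdhl, enzymes of isoprenoid and sterol synthesis, fell by 2.28 ± 0.36 (4.85-fold, adjusted p = 0.0149) and 2.19 ± 0.34 (4.55-fold, adjusted p = 0.0148). Hsd17b7, another sterol enzyme, fell by 1.18 ± 0.17 (2.26-fold, adjusted p = 0.0125), and Cyp51 and Fdps, the lanosterol demethylase and the farnesyl diphosphate synthase, by 2.36 ± 0.42 and 2.13 ± 0.38. Second probes of Hmgcs1 and Nsdhl gave -2.34 and -2.15. Sqle, the squalene epoxidase, had the largest difference of the fixed genes (-2.84 ± 0.59) and missed the threshold (adjusted p = 0.0559).

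The mean of the cholesterol list lay between 1.32 and 2.34 on the 5 HFHS arrays and between 3.01 and 3.61 on the 3 ST vehicle arrays. Camera called the list lower (mean log2 fold change -1.39, adjusted p = 9.08e-30). The call was lost with an estimated correlation (adjusted p = 0.122 with an estimated correlation), while fry, which does not compare the list with other genes, gave an adjusted p of 0.00323. The exact two-sided permutation test of the list mean gave p = 0.0179, the smallest that 56 splits allow (0.286 adjusted over the 32 lists). Acss2, the cytosolic acetyl-CoA synthetase and the only called member of the 17 measured lipogenesis genes (also 1 adjusted over the list alone), fell by 1.76 ± 0.29 (adjusted p = 0.0216). Rdh11, a retinol dehydrogenase, fell by 2.03 ± 0.24 (4.08-fold, adjusted p = 0.00705). The fatty acid enzymes Fasn (-1.05 ± 0.36, adjusted p = 0.244) and Scd1 (0.04 ± 0.37) and the regulator Srebf1 (0.44 ± 0.27) did not pass.

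**Figure D1:**
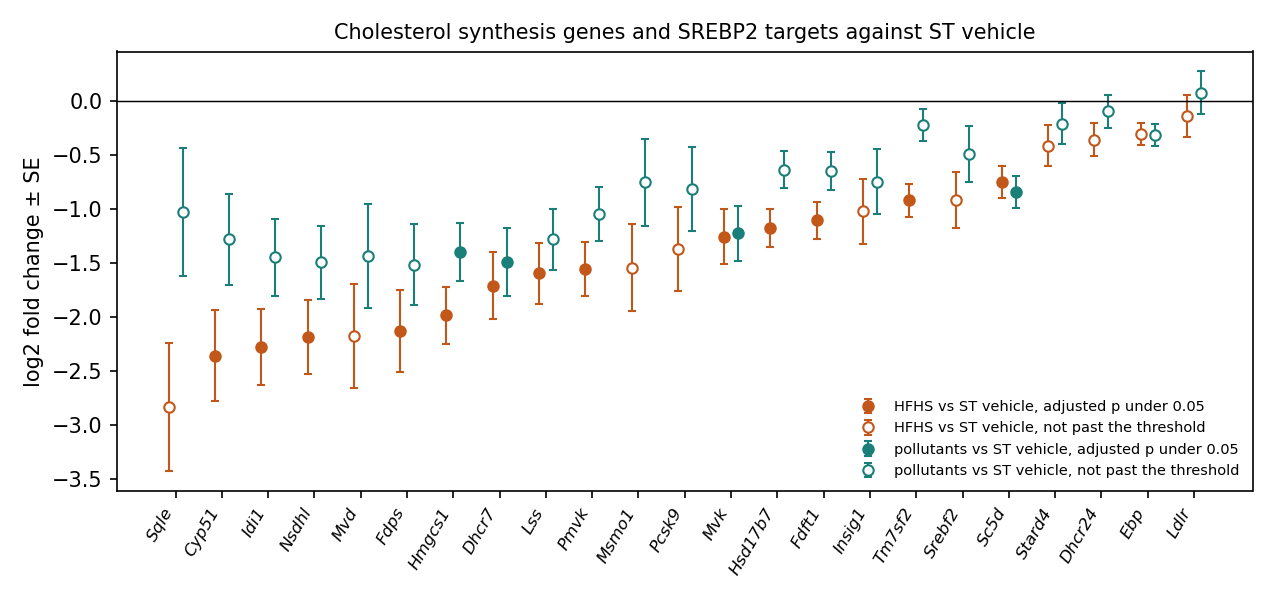
Log2 fold change with its standard error (y axis) of 23 of the 24 measured genes of cholesterol synthesis and SREBP2 targets (x axis), for HFHS (n = 5) and pollutants (n = 5) against ST vehicle (n = 3). Filled points passed an adjusted p of 0.05, which 13 genes did in HFHS and 4 in pollutants.

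Mogat1, Cd36, Cyp7a1, Sema5b and Krt23 were among the genes that rose on the high-fat diet. Mogat1, a monoacylglycerol acyltransferase of triglyceride synthesis, rose by 2.58 ± 0.49 (5.98-fold, adjusted p = 0.0398), and Cd36, a fatty acid transporter, by 0.93 ± 0.19 (1.90-fold, adjusted p = 0.0458). They were the 2 called members of the 17 genes of the lipid droplet and PPARgamma list (7 higher and 2 lower adjusted over the list alone), which camera called higher (adjusted p = 0.00422; adjusted p = 0.481 with an estimated correlation). Cd36 was also the 1 called gene of the 33 PPARalpha targets and fatty acid oxidation genes (5 higher adjusted over the list alone), a list camera called higher (adjusted p = 2.40e-06; adjusted p = 0.561 with an estimated correlation). Normexp background correction ended both list calls (adjusted p = 0.0610 for lipid droplets and 0.184 for PPARalpha targets). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.99 ± 0.29 (3.96-fold, adjusted p = 0.0125) and was the only called gene of the 17 in its list (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.885), in which 11 of 17 genes were negative. Among the named genes the largest rise was that of Sema5b, a semaphorin (mm9 chromosome 16, 35664281 to 35664340), at 2.78 ± 0.33 (6.88-fold, adjusted p = 0.00705), with 2.82 to 3.41 within the 3 slides that held both groups. Its other probes gave 0.50 and 2.80. The keratin gene Krt23 rose by 2.27 ± 0.33.

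Among the other genes that fell, the receptor gene Adgrf1 fell by 2.99 ± 0.34 (7.93-fold, adjusted p = 0.00705), Nfe2 by 2.70 ± 0.36 (6.48-fold, adjusted p = 0.0110), Tafa2 by 1.99 ± 0.37 and Id1, an inhibitor of helix-loop-helix transcription factors, by 1.90 ± 0.23 (3.72-fold, adjusted p = 0.00705). Cyp1a2, a xenobiotic cytochrome and the 1 called gene of the 6 measured AhR targets (2 lower adjusted over the list alone), fell by 0.87 ± 0.17 (1.82-fold, adjusted p = 0.0401). Of the 23 measured CAR and PXR targets, Alas1, the first enzyme of heme synthesis, rose by 1.48 ± 0.21 (2.78-fold, adjusted p = 0.0115) and the carboxylesterase Ces2a fell by 0.73 ± 0.12 (1.66-fold, adjusted p = 0.0229). Adjusted over the list alone, 3 of them were higher and 6 lower. The clock genes moved in opposite directions: Per2 rose by 1.63 ± 0.29 (3.09-fold, adjusted p = 0.0258), Arntl fell by 1.60 ± 0.28 (3.03-fold, adjusted p = 0.0242), and Usp2, a deubiquitinase with a daily rhythm, rose by 1.86 ± 0.32. Of the 15 measured clock genes, 7 were higher and 3 lower adjusted over the list alone, and camera called the list higher (adjusted p = 0.00422; adjusted p = 0.481 with an estimated correlation). That call was lost without ST vehicle replicate 3 (adjusted p = 0.0588), without the 3 HFHS arrays high in acinar transcripts (0.152) and with normexp background correction (0.0610), and the list differed by 0.19, 0.01 and 0.82 within slides 1, 2 and 5. Clstn3, Pdxp and Radx completed the 10 named genes that rose, Clstn3 at 1.58 ± 0.32 and Pdxp at 1.57 ± 0.30 (its other probe at 0.17). Radx was at background on all 3 ST vehicle arrays and at least 2.37-fold higher in HFHS.

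Transcripts of other cell types differed between the same arrays. The 9 measured markers of pancreatic acinar cells had list means of 3.64 to 6.97 on HFHS replicates 3, 4 and 5 and of -2.71 and -2.44 on HFHS replicates 1 and 2, against -2.75 to -2.24 in ST vehicle. Camera called this list higher (mean log2 fold change 4.56, adjusted p = 1.90e-06; adjusted p = 0.496 with an estimated correlation), with 0 genes called and 6 higher adjusted over the list alone. Without these 3 arrays the call was lost (adjusted p = 0.806).

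Several other lists without a called member were called by camera and lost that call when single arrays were left out. ER stress and amino acid response was called lower (16 of 17 genes negative, adjusted p = 0.000463; adjusted p = 0.481 with an estimated correlation), with 0.0696 without ST vehicle replicate 2. Hepatocyte markers were called lower (mean -0.23, adjusted p = 0.0228; 0.584 with an estimated correlation), with 0.0988, 0.0807 and 0.114 without HFHS replicates 1 and 3 and ST vehicle replicate 3, 0.0693 without slide 1, 0.213 with quantile normalization and 0.254 in the authors' table. Cholangiocyte markers were called lower (mean -0.50, adjusted p = 0.0244; 0.481 with an estimated correlation), with 0.0599 and 0.0894 without ST vehicle replicates 1 and 2 and 0.384 with normexp background correction. The male-biased liver genes were called lower (adjusted p = 0.0433; 0.869 with an estimated correlation) under 14 of 29 other settings. ST vehicle replicate 3 stood apart in them (3.47 against 1.80 and 2.07), and without it the direction turned and the call was lost (adjusted p = 0.693). Their call was also lost with slide as a block (0.225), the differences within slides 1, 2 and 5 being 0.33, -0.27 and -1.39, and without HFHS replicates 1, 2 and 3 (0.0939, 0.0673 and 0.192) and pollutant replicates 2 and 4 (0.0546 and 0.0508). The 4 measured erythroid markers were called higher as a list (mean 0.33, adjusted p = 0.0433; 0.561 with an estimated correlation), also under 14 of 29 settings. This was lost with slide as a block (0.0886), without HFHS replicates 1, 4 and 5 (0.0988, 0.106 and 0.0911), without ST vehicle replicates 2 and 3 (0.113 and 0.186) and without pollutant replicate 4 (0.0508). Among the 22 lists not called, the smallest adjusted p was that of the skeletal muscle markers (mean -1.79, adjusted p = 0.0650), whose means ranged from -5.24 to -0.89 over the HFHS arrays. Of the fixed genes not yet given, Cyp2b10 (0.20 ± 0.15), Cyp3a11 (0.06 ± 0.16, other probe -0.16), Cyp4a10 (0.63 ± 0.34), Cyp4a14 (0.68 ± 0.36), Pparg (0.35 ± 0.13), Cidea (-0.54 ± 1.14), Cidec (0.46 ± 0.45, other probe 0.13), Fgf21 (-0.46 ± 0.62), Esr1 (0.15 ± 0.21) and Sult1e1 (-0.66 ± 0.91) did not pass.

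In total 46 genes were higher and 88 lower in HFHS than in ST vehicle at an adjusted p under 0.05, 19 and 41 of them by at least 2-fold, and 2356 genes had an unadjusted p under 0.05. All 26 named genes that passed had the same sign within each of slides 1, 2 and 5. The rule for named genes favours this, since those of largest change needed the same sign in every array of the changed group. Of the 26, 18 passed with slide as a block, in which 35 genes were higher and 49 lower. Usp2, Per2, Arntl, Cd36, Pdxp, Radx, Tafa2 and Hsd17b7 did not (adjusted p = 0.0967, 0.105, 0.0927, 0.156, 0.0665, 0.0915, 0.122 and 0.0519). The counts depended on single arrays: 8 higher and 15 lower genes were called without ST vehicle replicate 1, 30 and 26 without replicate 2, 14 and 28 without replicate 3, 23 and 57 without HFHS replicate 2, and 21 and 47 without HFHS replicate 5, while 26 were higher without HFHS replicate 3 and 56 lower without HFHS replicate 4. Without the 3 HFHS arrays high in acinar transcripts, limma called 4 genes (Sema5b and Clstn3 higher, Ocln and Cd207 lower), with 1899 at an unadjusted p under 0.05, and without the arrays of slide 1 it called 1, Id1, with 1864. Ocln and Cd207 were named after their values were seen.

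The second comparison asked what the pollutant mixture changed on the standard diet, pollutants against ST vehicle (n = 5 and 3). Clock genes were among the genes that changed. Of the 15 measured clock genes, 5 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone. Ciart, a repressor of the clock, rose by 2.88 ± 0.49 (7.36-fold, adjusted p = 0.0220), Per2 by 1.85 ± 0.29 (3.62-fold, adjusted p = 0.0158) and Per1 by 1.47 ± 0.27 (2.77-fold, adjusted p = 0.0302), while Arntl, the activator that peaks opposite to them, fell by 2.13 ± 0.28 (4.36-fold, adjusted p = 0.00636). A second Per1 probe gave -0.01. Nr1d1, another repressor of the clock, was at -1.02 ± 0.31 and did not pass (adjusted p = 0.170). Usp2 rose by 2.70 ± 0.32 (6.49-fold, adjusted p = 0.00381) and Wee1, a cell cycle kinase under clock control, by 1.35 ± 0.24 (adjusted p = 0.0245). Camera called the clock list higher (mean 0.49, adjusted p = 0.000195; adjusted p = 0.274 with an estimated correlation), and the exact permutation test of its mean gave p = 0.0179, the smallest possible (0.191 adjusted over the 32 lists).

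**Figure D2:**
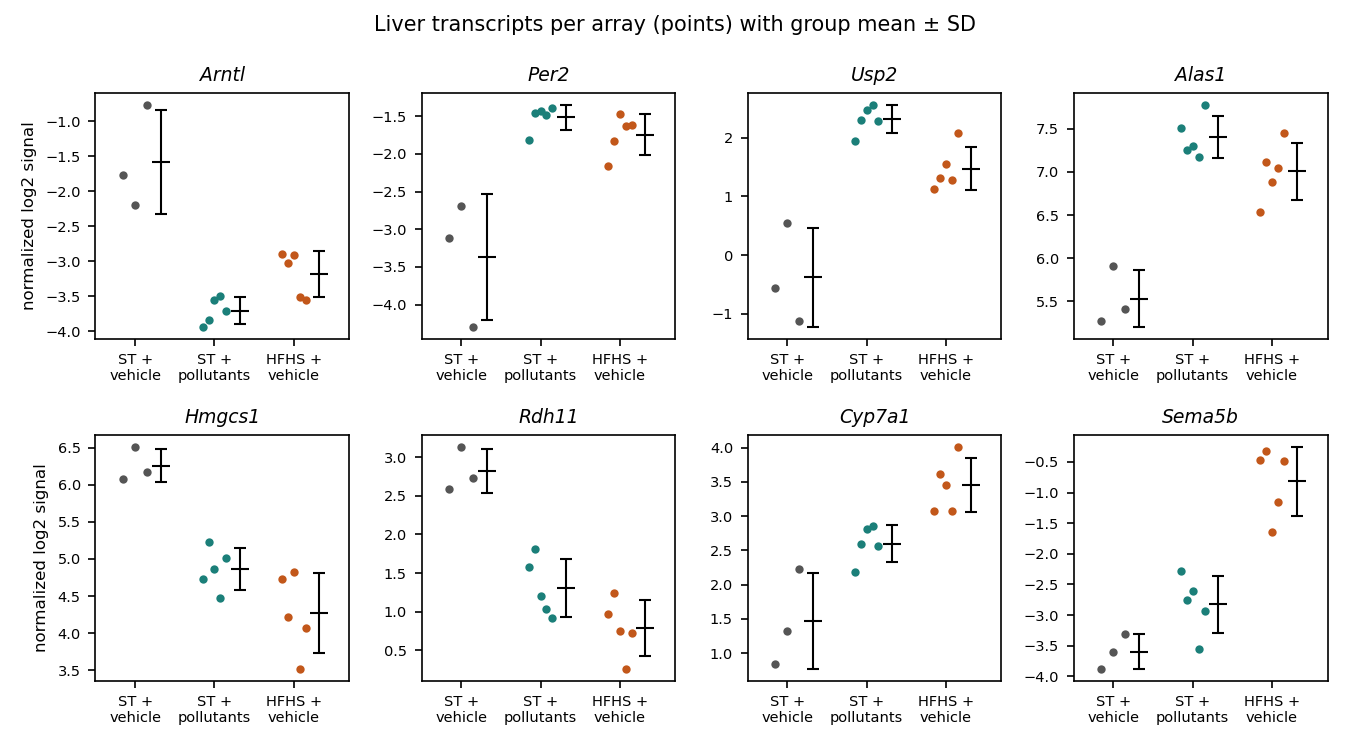
Normalized log2 signal (y axis) of 8 named genes on each array (points) with the group mean and SD (bars), for ST vehicle (n = 3), pollutants (n = 5) and HFHS (n = 5). Arntl lay at -1.58 ± 0.74 in ST vehicle, -3.71 ± 0.19 in pollutants and -3.18 ± 0.33 in HFHS.

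Most genes of cholesterol synthesis had negative fold changes under the mixture as well. Of the 24 genes 4 fell and 0 rose, and 15 fell adjusted over the list alone. Dhcr7, the last enzyme of the Kandutsch-Russell branch, fell by 1.49 ± 0.31 (2.81-fold, adjusted p = 0.0483), Hmgcs1 by 1.40 ± 0.27 (2.63-fold, adjusted p = 0.0342), the mevalonate kinase Mvk by 1.23 ± 0.25 (2.34-fold, adjusted p = 0.0456) and Sc5d by 0.84 ± 0.15 (1.79-fold, adjusted p = 0.0245). List means were 2.14 to 2.64 on the pollutant arrays, all below the lowest ST vehicle array (3.01). Camera called the list lower (mean -0.86, adjusted p = 6.51e-15; adjusted p = 0.274 with an estimated correlation), and the exact permutation test gave p = 0.0179 (0.191 adjusted over the 32 lists). Fry gave an adjusted p of 0.0561. Sqle (-1.03 ± 0.59) did not pass. Acss2 fell by 1.51 ± 0.29 (2.84-fold, adjusted p = 0.0345), as the 1 called member of the 17 lipogenesis genes, a list called lower (adjusted p = 0.0216; adjusted p = 0.909 with an estimated correlation). That list call was lost with slide as a block (0.0977; slide 1 at 0.13, slides 2 and 5 at -0.22 and -0.39) and without ST vehicle replicate 2 (0.719), pollutant replicate 4 (0.145) or pollutant replicate 5 (0.105). Rdh11 fell by 1.51 ± 0.24. Fasn (-0.90 ± 0.36), Scd1 (-0.20 ± 0.37) and Srebf1 (-0.27 ± 0.27) did not pass.

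Most genes of fatty acid oxidation had positive fold changes, but few passed. Of 33 PPARalpha targets and fatty acid oxidation genes 2 rose, the thioesterase Acot4 by 0.95 ± 0.17 (1.93-fold, adjusted p = 0.0290) and the carnitine transporter Slc22a5 by 0.84 ± 0.18 (1.79-fold, adjusted p = 0.0490), and 11 were higher adjusted over the list alone. Camera called the list higher (mean 0.51, adjusted p = 6.65e-14; adjusted p = 0.274 with an estimated correlation), with 31 of 33 genes positive. Fry gave an adjusted p of 0.0561, and the exact permutation test gave p = 0.0357 (0.286 after adjustment). Cyp4a10 (0.81 ± 0.34) and Cyp4a14 (1.01 ± 0.36), targets of the same receptor, did not pass. The related thioesterase Acot5 rose by 1.35 ± 0.24 (adjusted p = 0.0256), its second probe at -0.19. The lipid droplet list held no called gene (3 higher adjusted over the list alone) and was called higher (mean 0.50, adjusted p = 0.000159; adjusted p = 0.274 with an estimated correlation), with Cidec at 1.32 ± 0.45, Cidea at 1.08 ± 1.14, Cd36 at 0.36 ± 0.19 and Pparg at 0.21 ± 0.13, none past the threshold. A second Cidec probe gave 0.32. The Cidea value came from pollutant replicate 2 alone (-0.002 without it), the array with the highest mean of adipocyte markers (0.11).

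The fixed genes of xenobiotic metabolism gave little. Of the 23 CAR and PXR targets, Alas1 rose by 1.88 ± 0.21 (3.67-fold, adjusted p = 0.00358) and Por, the cytochrome P450 reductase, by 0.87 ± 0.16 (1.83-fold, adjusted p = 0.0312), with 4 higher and 1 lower adjusted over the list alone, and the list was not called (adjusted p = 0.258). Cyp2b10 (-0.03 ± 0.15), Cyp3a11 (0.10 ± 0.16, other probe -0.10) and Cyp1a2 (-0.35 ± 0.17) did not pass, and the upper ends of the 95% intervals of Cyp2b10 and Cyp3a11 lie at log2 fold changes of 0.29 and 0.45. None of the 6 AhR targets was called. Abcb11, the bile salt export pump, fell by 0.52 ± 0.08 (1.43-fold, adjusted p = 0.0197), and Cyp7a1 was at 1.14 ± 0.29 (adjusted p = 0.0982). Of 7 periportal markers the cadherin Cdh1 fell by 0.99 ± 0.20. Other named genes that rose were the lysolipid transporter Mfsd2a (1.80 ± 0.33), the folate enzyme Mthfd1l (1.53 ± 0.17, adjusted p = 0.00358) and Coq10b (1.36 ± 0.24). Gngt1 (fell by 1.89 ± 0.29), Asap2 (by 1.58 ± 0.30), Spon2 (by 1.47 ± 0.29) and the manganese transporter Slc30a10 (by 1.45 ± 0.20) fell. Fgf21 (0.29 ± 0.62), Esr1 (0.24 ± 0.21) and Sult1e1 (-0.97 ± 0.91) did not pass.

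Camera also called lower ER stress and amino acid response (1 of 17 lower adjusted over the list alone, adjusted p = 0.00710; 0.625 with an estimated correlation), with an adjusted p of 0.332 without ST vehicle replicate 2. Cell cycle genes were called lower (0 of 14 called, adjusted p = 0.00868; 0.909 with an estimated correlation), yet the list was higher within slides 1 and 2 (0.14 and 0.65) and lower only within slide 5 (-1.78). ST vehicle replicate 3 stood apart in it (-0.02 against -1.40 and -1.94), without that array the direction turned and the call was lost (0.897), and it was lost with slide as a block (0.0977). The 4 erythroid markers were called higher (mean 0.52, adjusted p = 0.00336; 0.297 with an estimated correlation), with 3 higher adjusted over the list alone. Pancreatic acinar markers did not differ past the threshold (mean -0.08, adjusted p = 0.996), nor did those of skeletal muscle (mean 0.34, adjusted p = 0.928), which varied from -3.57 to -0.79 within the pollutant arrays and from -3.86 to -1.20 within ST vehicle. The adjusted p of the 24 lists not called lay between 0.147 and 0.996.

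In total 106 genes were higher and 86 lower under pollutants, 27 and 29 of them by at least 2-fold, and 2370 genes had an unadjusted p under 0.05. All 27 named genes that passed had the same sign within each of slides 1, 2 and 5, which the rule for named genes favours. With slide as a block 32 genes were higher and 35 lower, and 11 of the 27 passed (Usp2 at an adjusted p of 0.0295, Arntl at 0.0379, Alas1 at 0.0140). The other 16 did not, among them Ciart, Per2, Per1, Hmgcs1, Dhcr7 and Mvk (0.0786, 0.0678, 0.0678, 0.0624, 0.0678 and 0.0958). The counts fell to 17 higher and 22 lower without ST vehicle replicate 1, to 53 and 23 without replicate 2, to 20 and 26 without replicate 3, to 54 and 44, 48 and 41, and 52 and 39 without pollutant replicates 3, 4 and 5, to 69 and 48 without HFHS replicate 2, and to 51 lower without pollutant replicate 1. Without the arrays of slide 1 limma called 3 genes, Id1, Id2 and Gstp3 (the last 2 named after their values were seen), all lower, with 2078 at an unadjusted p under 0.05.

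The third comparison asked which features both treatments shared. In both comparisons with ST vehicle 45 genes passed in the same direction, 19 higher and 26 lower, and 0 in opposite directions. Usp2, Per2 and Alas1 rose in both, and Arntl, Rdh11, Hmgcs1, Acss2 and Id1 fell in both, Id1 by 1.38 ± 0.23 under pollutants. Independent lists of these sizes would share 0.25 higher and 0.39 lower genes. Both comparisons use the same 3 controls, however, and 100 simulations of unchanged groups against shared controls gave a correlation of 0.624 between the fold changes across genes, against 0.438 observed, and 0 shared calls. These simulations drew every array independently and left out the slide, so their 0 is not a bound for the 45: other splits of the real arrays gave up to 33 shared genes. The covariance of the fold changes exceeded that of the simulations by 0.0024 (0.0416 against 0.0392). Of the 134 genes called in HFHS, 38 also differed in the same direction from pollutants, and of the 192 called under pollutants, 56 differed in the same direction from HFHS. Of the 45 shared genes, 2 differed between the treatments, Leo1 and Lonrf1 (named after their values were seen), both farther from ST vehicle under pollutants (Lonrf1 0.86 against 0.47, Leo1 -1.03 against -0.61). The shared count fell to 4, 23 and 14 without ST vehicle replicates 1, 2 and 3, to 25, 28 and 23 without HFHS replicates 2, 3 and 5, to 24, 26 and 23 without pollutant replicates 3, 4 and 5, and to 22 with slide as a block. It was 0 by limma without the 3 HFHS arrays high in acinar transcripts (1899 and 2211 genes at an unadjusted p under 0.05 in the 2 comparisons), 1 without the arrays of slide 1 (Id1) and 5 with normexp background correction (Abca8b, Id1, Id3, LOC102633223 and Osbpl5), and the 4 left without ST vehicle replicate 1 were Abca8b, LOC102633223, Marveld1 and Niban2 (all named after their values were seen).

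The direct comparison of both treatments, HFHS against pollutants (n = 5 each), tested where they differed. It does not tell which of them departed from ST vehicle. Pck1, Igfbp1, Gys2 and Pnpla2 were lower in HFHS than in pollutants and Pklr was higher. The ST vehicle arrays lay at 4.98 to 5.35 for Gys2 and 6.46 to 6.70 for Pck1, below every pollutant array (lowest 5.57 and 7.13). For Igfbp1 they lay at 4.87 to 5.08, above every HFHS array (highest 3.745). Of the 17 genes of glucose metabolism and insulin response 3 were lower and 0 higher (4 lower and 2 higher adjusted over the list alone). Pck1, the gluconeogenic carboxykinase, was lower by a log2 difference of -1.10 ± 0.20 (2.14-fold, adjusted p = 0.0102), Igfbp1, an insulin-repressed binding protein, by -1.94 ± 0.49 (3.84-fold, adjusted p = 0.0486) and the glycogen synthase Gys2 by -0.74 ± 0.19 (1.67-fold, adjusted p = 0.0498), and the list was not called (adjusted p = 0.273). The triglyceride lipase Pnpla2 was lower (-0.64 ± 0.10, adjusted p = 0.00586), the 1 called gene of the 17 in the lipid droplet list (2 higher and 3 lower adjusted over the list alone). The pyruvate kinase Pklr, of the lipogenesis list, was higher (0.45 ± 0.11, adjusted p = 0.0497). Tm7sf2, a sterol reductase, was lower (-0.70 ± 0.13, 1.62-fold, adjusted p = 0.0131) and was the 1 called gene of the 24 of cholesterol synthesis, of which 6 were lower adjusted over the list alone. Camera called that list lower in HFHS (mean -0.53, adjusted p = 1.30e-05; adjusted p = 0.911 with an estimated correlation).

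The CAR and PXR targets were called lower in HFHS as a list (mean -0.23, adjusted p = 0.00444; adjusted p = 0.889 with an estimated correlation), with Ces2a at -0.73 ± 0.11 (1.65-fold, adjusted p = 0.00586) the 1 called gene of 23 and 5 lower adjusted over the list alone. So were the PPARalpha targets (mean -0.23, adjusted p = 0.00906; adjusted p = 0.917 with an estimated correlation), with Slc22a5 at -0.66 ± 0.15 (adjusted p = 0.0350) the 1 called gene of 33. The PPARalpha call was lost without HFHS replicate 4 (0.128), without pollutant replicate 5 (0.279), without the 3 HFHS arrays high in acinar transcripts (0.121) and with quantile normalization (0.124), and the list was positive within slides 2 and 3 (0.09 and 0.06). Quantile normalization also ended the call of the CAR and PXR targets (0.0518). Interferon response genes were called higher (17 of 19 positive, 0 called, mean 0.23, adjusted p = 0.00300; adjusted p = 0.917 with an estimated correlation), with 0.131 without pollutant replicate 4 and 0.0958 with normexp background correction. Acinar markers were called higher (mean 4.63, adjusted p = 1.30e-05; adjusted p = 0.889 with an estimated correlation; 9 higher adjusted over the list alone), on the same HFHS replicates 3, 4 and 5, without which the call was lost (0.948). Per1 was lower (-1.02 ± 0.24, adjusted p = 0.0359; its other probe at -0.07), Baat, which conjugates bile acids, higher (0.32 ± 0.07, adjusted p = 0.0315), and the prolactin receptor Prlr higher (0.56 ± 0.12, adjusted p = 0.0269; its other probe at 0.19). The 27 lists not called had an adjusted p between 0.0705 (oxidative phosphorylation) and 0.982.

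**Figure D3:**
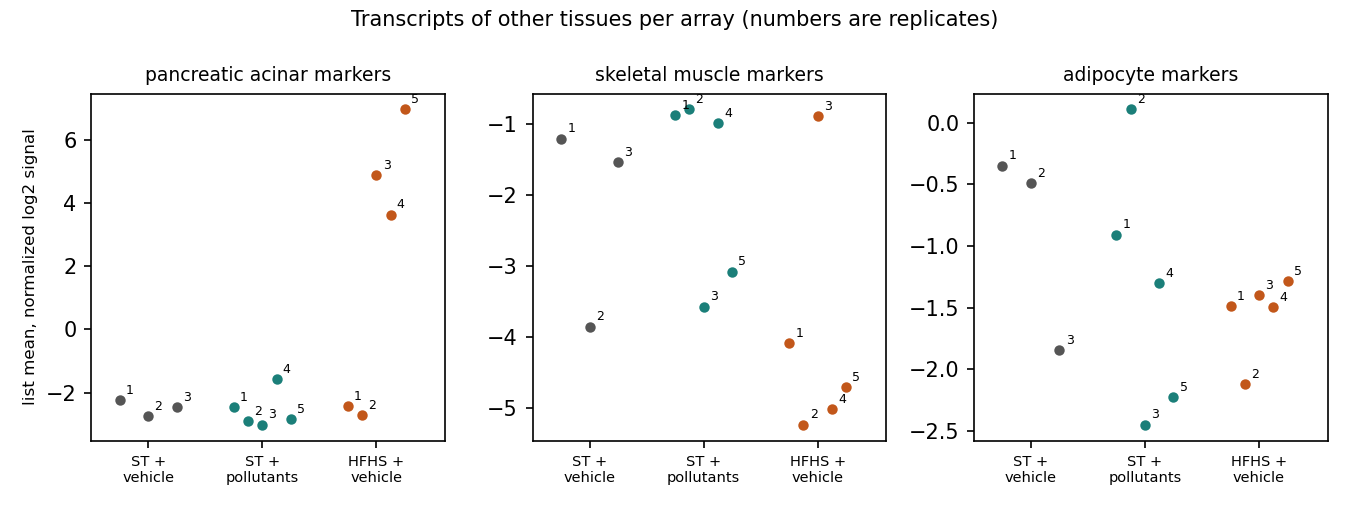
List mean of the normalized log2 signal (y axis) of pancreatic acinar, skeletal muscle and adipocyte markers on each array (points, numbered by replicate) in the 3 groups. The acinar markers of HFHS replicates 3, 4 and 5 lie between 3.64 and 6.97 and those of the other 10 arrays between -3.02 and -1.56.

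Of the largest differences, Sema5b was higher in HFHS (2.01 ± 0.28, 4.03-fold, adjusted p = 0.00586; other probes at 0.38 and 1.95), as were Hao2, a peroxisomal hydroxyacid oxidase (1.71 ± 0.37, 3.26-fold, adjusted p = 0.0281), the receptor subunit Grin3b (1.71 ± 0.25), the potassium channel Kcnk10 (1.496 ± 0.258), Mansc4 (1.25 ± 0.23), Snap25 (1.20 ± 0.20) and Car3, a carbonic anhydrase abundant in fat and in rodent liver (1.20 ± 0.22), the 1 called gene of 5 adipocyte markers. Pign (1.45 ± 0.22), Marchf1 (1.26 ± 0.23) and Slc17a5 (1.19 ± 0.21) were called on 1 probe each, while a second probe gave -0.22, -0.06 and 0.10. Lower in HFHS were Tafa2 (-1.77 ± 0.32, adjusted p = 0.0102), the transcription factor Zbtb16 (-1.64 ± 0.33, adjusted p = 0.0195), Srrm4 (-1.57 ± 0.37), Smad9 (-1.54 ± 0.35), Cib3 (-1.53 ± 0.28), Adgrf1 (-1.42 ± 0.30) and Mfsd2a (-1.39 ± 0.29). Pip5k1a (-1.82 ± 0.44) had 2 further probes at -0.06 and -0.04. Blcap (-1.32 ± 0.21) and Cyp2u1 (-0.81 ± 0.14, of the male-biased list, its second probe at 0.01) belong to 99 called genes that varied almost as one within the groups. The first component of the deviations from the group means was taken over all 756 called genes (27.6% of the variance). Each of the 99 genes correlated with it above 0.9 in size, with a sign that had to go with the direction of its call. The second probes of 34 of these genes had a median change of -0.001 in the direction of the first, whose median was 1.09. For 29 other called genes of the same size of change the second probes had a median of 0.10. Below the cutoff of 0.9, Pck1, Igfbp1 and Gys2 correlated with the same first component at -0.778, -0.807 and -0.795. Pign, Marchf1, Snap25 and Slc17a5 correlated with it at 0.801, 0.778, 0.768 and 0.845. A second Gys2 probe gave a difference of -0.88, near that of the first.

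Of the fixed genes none passed here. Cyp7a1 (0.85 ± 0.25, adjusted p = 0.0907), Cyp1a2 (-0.52 ± 0.15, adjusted p = 0.0741), Cd36 (0.57 ± 0.16, adjusted p = 0.0741), Sqle (-1.81 ± 0.51, adjusted p = 0.0772) and Srebf1 (0.71 ± 0.23) had the smallest p-values. Cyp2b10 (0.23 ± 0.13), Cyp3a11 (-0.04 ± 0.14), Cyp4a10 (-0.18 ± 0.29), Cyp4a14 (-0.33 ± 0.31), Fasn (-0.14 ± 0.31), Scd1 (0.24 ± 0.32), Pparg (0.14 ± 0.12), Cidea (-1.62 ± 0.99), Cidec (-0.86 ± 0.39, other probe -0.19), Fgf21 (-0.75 ± 0.54), Esr1 (-0.10 ± 0.18) and Sult1e1 (0.30 ± 0.79) lay farther from the threshold.

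In total 307 genes were higher and 449 lower in HFHS than in pollutants (41 and 103 by at least 2-fold, 3567 at an unadjusted p under 0.05), or 306 and 351 without the 99 genes that varied as one. With normexp background correction 87 were higher and 205 lower, a share of 29.8% higher against 40.6%, and 28 of the 756 called genes had the opposite sign. Of the 31 named genes that passed, 29 had the same sign within each of the 5 slides (Igfbp1 and Srrm4 differed on slide 3, at 0.07 and 0.49), which the rule for named genes favours. With slide as a block 24 of the 31 passed and 7 did not, and this fit gave 295 higher and 494 lower genes. The counts fell to 143 higher and 248 lower without HFHS replicate 1, to 122 and 227 without HFHS replicate 2, to 175 higher without HFHS replicate 3, and to 156 and 275, 171 and 298, and 194 and 285 without pollutant replicates 3, 4 and 5. Without the arrays of slide 1 limma called 1 unnamed transcript, which was lower, with 2835 genes at an unadjusted p under 0.05.

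Mean, median and camera direction differed in sign for some of the lists not called. For HFHS against ST vehicle these were glucose metabolism, acute phase, female-biased genes, oxidative phosphorylation and endothelial markers. For pollutants against ST vehicle they were female-biased genes and the markers of endothelial cells, cholangiocytes and acinar cells. For HFHS against pollutants they were bile acid synthesis, female-biased genes and the markers of neutrophils, endothelial cells and adipocytes. None of the 32 lists was called in any comparison with an estimated correlation. The exact permutation test called none after adjustment. Against ST vehicle it could hardly do so, since 56 splits allow no p under 0.0179. Many lists would have had to reach that value together to pass, so this result is weak evidence against the lists. The smallest adjusted p of the permutation test was 0.286 for HFHS against ST vehicle, 0.191 for pollutants against ST vehicle and 0.339 for HFHS against pollutants. Given as mean log2 fold changes, bile acid synthesis (-0.03, -0.02 and -0.01 for HFHS against ST vehicle, pollutants against ST vehicle and HFHS against pollutants), NRF2 genes (-0.16, -0.07 and -0.10), acute phase genes (0.02, 0.10 and -0.08), fibrosis genes (-0.11, -0.12 and 0.01), estrogen and steroid handling (-0.13, -0.25 and 0.12), pericentral markers (-0.01, 0.02 and -0.03), Kupffer cell markers (0.03, 0.09 and -0.06), T cell markers (-0.18, -0.14 and -0.04), B cell markers (-0.06, -0.15 and 0.09), neutrophil markers (-0.23, -0.20 and -0.03) and endothelial markers (0.01, 0.01 and 0.00) did not pass in any comparison. Nor did AhR targets (-0.165, -0.04 and -0.13), female-biased genes (-0.11, -0.22 and 0.11), oxidative phosphorylation (0.01, -0.06 and 0.07), periportal markers (-0.29, -0.175 and -0.12) and adipocyte markers (-0.66, -0.46 and -0.20).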

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

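The tests of the 3 patterns weighed here were all chosen only after the patterns had been seen, and apart from that for whole pancreas their predictions were written after values were known. Of 181 groups of 5 values of array measures, named genes and lists, 10 held a sample far from the others (5.5%), and chance does so in about 1 in 20 groups.

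Pancreatic acinar transcripts were high in HFHS replicates 3, 4 and 5 only. RNA from pancreatic acinar tissue could account for them: of 15 acinar genes outside the fixed list, 14 had their 3 highest arrays there, against 0.052 expected by chance, and the 9 list members differed between these arrays by nearly the same amount (SD 0.164 to 0.327). Whether it had a single source cannot be told, since acinar tissue of like composition from several sources could give the same differences. The 3 arrays were picked for high acinar markers, so the chance value is not a fair bound for related genes. Carry-over of whole pancreas cannot be told apart from acinar material alone, since 1 of 8 islet genes (Ins1) had its 3 highest arrays there, while on HFHS replicate 5, the array highest in acinar transcripts, Ins1, Ins2, Gcg and Iapp stood above every other array (1.376, 2.004, -2.75 and -1.347, next highest -2.729, -0.676, -5.414 and -5.739). The test of acinar genes taken separately was added after that. Acinar transcripts were not high in every HFHS animal (3 of 5 HFHS arrays above the highest ST vehicle array). That count restates the pattern itself, which an effect of the diet in every animal would not give. RNA of other organs in general did not account for the pattern (1 of the 6 highest muscle and adipocyte values on HFHS replicates 3, 4 and 5).

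Some clock genes were called in both groups against ST vehicle, Per2 and Arntl alone in HFHS, and 5 higher and 2 lower genes under pollutants. A shift in the phase of the clock may be involved, but the test leaves it open: of 9 genes that peak opposite to Arntl, chosen after values were seen, 8 were higher and Nr1d1 was lower in both groups, and 3 that peak with Arntl were lower, the means being apart by 1.446 log2 units in HFHS and 2.106 in pollutants. Sampling times are not given in the sources used here, so sampling time and treatment cannot be told apart as a source of such a shift. ST vehicle replicate 3 was not the whole cause, since 79.3% of the mean change remained without it, although only 3 of 9 calls did. The slide was not the cause, since 99.1% remained with slide as a block and 0 differences within a slide were opposite, although only 1 of 9 calls remained.

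Of the genes called between HFHS and pollutants, 99 varied as one (98 lower, 1 higher). Signal of single probes, not of the transcripts, could account for this: the other probes of 34 of these genes had a median change of -0.001 in the direction of the first (17 of the same sign), against 0.098 for 29 other called genes of the same size of change (23 of the same sign) and 0.257 for all 177 other called genes with another probe (150 of the same sign). Since the median of other genes of that size was also low on another probe, the low median does not by itself set these 99 apart. The upper quartile on other probes was 0.84 for those other genes and 0.158 for the set. The slide could not make the mean difference, since every slide held an array of each treatment. Within the 5 slides the mean difference of the 99 genes, turned to the direction of the calls, was 0.522 to 1.551. With slide as a block 98 of the 99 passed. The acinar material was not the cause, since HFHS replicates 1 and 2, without it, lay at least 1.237 log2 units from the pollutant mean.

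Each remaining value is that of a sample far from the other 4 of its group, on the normalized log2 scale. Esr1 was -0.961 in HFHS replicate 3 (others -1.318 to -1.279). Mansc4 was -3.839 in pollutant replicate 2 (others -5.019 to -4.683). Mfsd2a was 4.672 in pollutant replicate 5 (others 3.593 to 3.883). Per2 was -1.814 in pollutant replicate 1 (others -1.488 to -1.395). Pign was -2.325 in pollutant replicate 3 (others -3.302 to -3.038). Por was 6.225 in pollutant replicate 1 (others 5.835 to 5.936). Scd1 was 4.218 in pollutant replicate 5 (others 4.933 to 5.225). Slc17a5 was 1.329 in pollutant replicate 3 (others 0.344 to 0.603). Slc22a5 was 0.633 in pollutant replicate 5 (others -0.071 to 0.102). Zbtb16 was 1.404 in pollutant replicate 4 (others -0.679 to -0.144).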

How the results depend on the processing

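The 2 fits without whole sets of arrays were chosen only after the results had been seen. Of the 84 called values of named genes, 1632 of 2347 values under other settings stayed past the threshold and 715 kept their direction but not the threshold. Of the 51 values not called, 1363 of 1422 stayed so, 25 passed in the same direction and 34 moved, and 0 values of called genes reversed. The lower cholesterol list in HFHS was called under 28 of 29 settings. Quantile normalization, the authors' table, the filter on all 13 arrays and every probe tested moved no count by over 1.5 times. Between 62.8% and 69.5% of the probes were well above background per array. Counts are given as higher and lower genes for HFHS against ST vehicle (46 and 88), pollutants against ST vehicle (106 and 86), HFHS against pollutants (307 and 449), and genes shared by both comparisons with ST vehicle (45), and the cause was not tested except where samples or groups were left out.

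Normexp background correction gave 15 and 30, 13 and 9, 87 and 205, and 5 shared. In that fit the median log2 fold change over all genes was 0.086, -0.001 and 0.094 in the same order. The authors' table gave 50 and 84, 114 and 88, 255 and 359, and 58 shared. Its values correlated at 0.9996 to 0.9997 per array with normexp-corrected and quantile-normalized values. Normexp correction therefore did not lower the counts this far under every normalization. Scaling to the median gave 23 and 45, 25 and 23, 120 and 203, and 17 shared. No filter on dim probes gave 17 and 38, 38 and 32, 129 and 232, 16 shared, and 8 lists for HFHS against pollutants (5 in the main result). Slide as a fixed block gave 49 lower in HFHS, 32 and 35 under pollutants, and 22 shared, and slide as a random block 129 and 208, 221 and 226, 646 and 1006, and 125 shared. Samples of the same number share a slide in all pairs but those of ST vehicle replicate 3, whose correlations were -0.154 with HFHS and -0.168 with pollutants, while pairs on the same slide as an ST vehicle array gave 0.236 to 0.56 and 0.129 to 0.416, and the 5 same-slide pairs of HFHS and pollutants -0.023 to 0.518. The replicate block gave 19 and 34, 22 and 22, and 14 shared. Fits of only the 2 groups compared gave 8 and 17, 21 and 19, and 3 shared, with fewer samples to estimate the spread. A variance trend with robust moderation gave 71 higher in HFHS, 149 lower under pollutants and 79 shared. Array weights gave 479 and 731 for HFHS against pollutants and 9 lists. Camera with an estimated correlation called 0, 0 and 0 lists (10, 8 and 5 in the main result), with 1, 5 and 0 lists at an unadjusted p under 0.05, and fry called 1, 0 and 0.

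Without the arrays of slide 1, which leaves fewer samples, the counts were 0 and 1, 0 and 3, 0 and 1, and 1 shared (limma, with 1864, 2078 and 2835 genes at an unadjusted p under 0.05), with 9 lists for HFHS against pollutants. Without the 3 HFHS arrays high in acinar transcripts they were 2 and 2, 48 and 44, 91 and 198, and 0 shared (1899, 2211 and 3059 at an unadjusted p under 0.05). At an adjusted p under 0.1 they were 116 and 181, 224 and 220, 550 and 809, and 118 shared. At a fold of at least 1.5, 120 and 241 remained between HFHS and pollutants. Leaving out each array in turn gave 8 to 50 higher and 15 to 90 lower genes in HFHS, 17 to 95 and 22 to 80 under pollutants, 122 to 289 and 227 to 423 for HFHS against pollutants, 4 to 40 shared, and 7 to 11, 7 to 10 and 4 to 7 lists.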

Other observations

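Id1, Id3, Atoh8 and Smad7, which respond to BMP and SMAD signalling in many tissues, fell against ST vehicle in both treatments. They were chosen only after their values had been seen, and no list of such genes was fixed or tested. Both falls were measured against the same 3 ST vehicle arrays. Without ST vehicle replicate 1, or in fits of only the 2 groups compared, none of them passed in both comparisons. With normexp background correction only Id1 and Id3 did, and without the arrays of slide 1 only Id1. In HFHS, Id1 fell by 1.90 ± 0.23 (adjusted p = 0.00705), Atoh8 by 1.45 ± 0.18 (adjusted p = 0.00820), Smad7 by 1.35 ± 0.21 (adjusted p = 0.0147) and Id3 by 1.02 ± 0.15 (adjusted p = 0.0115). Under pollutants, Id3 fell by 1.23 ± 0.15 (adjusted p = 0.00381), Id1 by 1.38 ± 0.23 (adjusted p = 0.0199), Atoh8 by 1.06 ± 0.18 (adjusted p = 0.0199), Smad7 by 1.13 ± 0.21 (adjusted p = 0.0294) and Id2 by 1.27 ± 0.24 (adjusted p = 0.0307). Id2 missed the threshold in HFHS (-1.10 ± 0.24, adjusted p = 0.0635). Others did not pass in either: Hamp, the iron hormone gene that this pathway drives (-1.37 ± 0.54 and -1.96 ± 0.54), Id4 (-0.63 ± 0.24 and -0.41 ± 0.24) and Smad6 (-0.26 ± 0.18 and -0.22 ± 0.18). None of these differed between HFHS and pollutants (Id1 -0.52 ± 0.20, adjusted p = 0.177).

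Gstp3, a glutathione S-transferase also chosen after its values were seen, had the smallest p under pollutants (fell by 1.17 ± 0.10, adjusted p = 0.00172) and was higher in HFHS than in pollutants (0.76 ± 0.09, adjusted p = 0.00586). Lpin1, a phosphatidate phosphatase, was lower in HFHS than in pollutants (-1.26 ± 0.19, adjusted p = 0.00586). Pollutant replicate 2 held high values of 3 transcripts: Cidea 1.195 (other arrays -5.336 to -2.756), Klk1 4.05 (3.989 on HFHS replicate 5, high in acinar transcripts) and Chga 2.272 (other arrays at most -2.441).

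The splits of the arrays into other groups were fixed in advance. For HFHS against ST vehicle no other split called as many genes (134 called, highest other split 25, 1 of 56 splits as large, the real one). The same held for pollutants against ST vehicle (192 called, highest other 43, 1 of 56) and for the shared genes (45, highest other 33, 1 of 100). These shares are the smallest possible, and the splits were made without regard to the slide. With slide as a block the shared count was 22. Splits of all 13 arrays do not test whether 45 shared genes exceed what the common controls produce. For HFHS against pollutants the real groups also gave the most calls (756 called, 1 of 100), yet another split gave 566. That split set HFHS replicates 1, 4 and 5 with pollutant replicates 1 and 4 and so kept the arrays of each of slides 1 to 4 together, and with slide as a block the real groups gave 295 higher and 494 lower genes. Chance was not excluded for the number of lists called: 10 for HFHS against ST vehicle (highest other 16, 15 of 56 as large), 8 for pollutants against ST vehicle (highest other 15, 24 of 56) and 5 for HFHS against pollutants (highest other 16, 78 of 100).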
